A study of Rattus norvegicus with 12 samples.

How the data were processed

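Total RNA of L6 dorsal root ganglia, the clusters of sensory nerve cell bodies at that spinal level, was taken from male rats of the inbred strain Fischer 344. It was labelled with Cy3 and hybridised to 12 one-colour Agilent rat arrays, per the labels' protocols. The design text gives 3 groups of 4 rats, and the labels give each group 4 arrays. The group young_AL was 6 months old and fed ad libitum, old_AL was 25 to 28 months old and fed ad libitum, and old_CR was 25 to 28 months old and had been fed on 3 days a week from 6 weeks of age, which came to 40% caloric restriction. The array number in a name such as old_AL 1 is the replicate number in the labels' source names. The sample titles carry other numbers, which were not used.

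The deposited values are spot intensities on a linear scale that Agilent Feature Extraction 10.7 made from each scan, per the submitters' processing notes and the file headers. The processed intensity was already background-subtracted and detrended within an array by the authors' scanner software, per the file headers, and no scaling between arrays had been applied to it. The values in the deposited table of the whole series were those same intensities, with a largest difference of 0 from the processed signal of each array, so their scale is linear and they are not centred. Each array carried 58717 spots of gene probes and 4259 control spots, and the gene probe spots held 30367 distinct probes. Each file held a single array, with no pair of arrays identical over all probes, and the highest correlation between arrays was 0.995.

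Log2 of the processed intensity minus each array's 75th percentile of it was the value analysed. Control spots were left out, spots with an outlier flag were set to missing, saturated spots were kept, and replicate spots of a probe were averaged. A probe counted as well above background on an array where at least a share of 0.5 of its spots carried the scanner's flag for that, and probes well above background on fewer than 4 arrays were left out. A gene was represented by its brightest probe, and probes of one gene that disagreed are given beside the gene. Probe accessions were matched to symbols through a RefSeq table of the assembly GRCr8, used for names alone because the array files carry a tag of an older build. Of the 30367 probes, 17998 matched 15154 symbols, and 12369 did not and were tested under the accession in the files. Where no probe of a gene was well above background on any array of a group, the fold is printed as "at least". It sets the mean of the brighter group against the mean of the dimmer group, taking for each dim array the higher of the probe's own value and the lowest signal among probes well above background.

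Groups were compared with limma 3.58.1 (lmFit and eBayes, with a mean per group) in R 4.3.3, with the package data.table (version 1.17.8) for reading, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 3 comparisons were old_AL against young_AL, old_CR against old_AL and old_CR against young_AL, and all groups shared one estimate of the spread. Differences are on the log2 scale with the standard error of the fit, and n counts arrays. In all, 41 lists of pathway genes and of markers of cells that a ganglion could hold were fixed before the data were examined. They were tested with limma's camera at a preset correlation of 0.01 between genes, with the p-values adjusted over the 41 lists. The same test with an estimated correlation, and limma's fry, which asks whether a list's genes moved one way on balance without comparing them with other genes, were alternatives.

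The genes to be named were chosen by a rule fixed before the data were examined. It took, for each comparison, the 10 largest rises and the 10 largest falls among genes with a symbol that passed and whose groups did not overlap, or the 5 smallest p-values in a direction where fewer than 5 passed. It added up to 4 members of each list with the smallest p, and up to 10 genes that passed in opposite directions with age and with diet. The array of old_AL 1 stood apart from the other 11, so the whole analysis, with the rule for named genes and each alternative, was also run on the 11 other arrays. Leaving out each array in turn had been planned, and giving this leave-out the weight of a second fit was decided after the data were seen. Every value below is from one of these fits, named as 12 arrays or 11 arrays.

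Alternatives were quantile normalization, median centring, normexp background correction with an offset of 50, no filter on dim probes, probes well above background on every array, the mean of a gene's probes, every probe on its own, the series table, a fit of the compared groups alone, an intensity trend, array weights, the replicate number as a block, and each array left out. Normexp was run on the median spot signal because the files hold no column of mean signals. The arrays lie on 2 slides with a scan each. The young_AL arrays fill a row of the first slide, and the old_AL and old_CR arrays fill separate rows of the second, so slide and scan cannot be told apart from the difference between young and old. A slide block leaves the fit of old_CR against old_AL as it is by construction, and the fit of those groups alone stands for the value within the slide. On that slide old_AL fills row 1 and old_CR row 2, so row cannot be told apart from diet.

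The scripts were tested on simulated data with the real genes' means, 200 changed genes and 10 draws. With gene variances drawn from the fitted model, the 12-array fit recovered 40.8% of genes changed 2-fold in old_AL against young_AL, 44.0% in old_CR against old_AL and 46.0% in old_CR against young_AL, over 19893 genes. The 11-array fit recovered 84.9%, 82.1% and 82.7% over 20785 genes. False calls were 4.58%, 5.92% and 5.32% of calls on 12 arrays and 5.04%, 5.54% and 4.76% on 11 arrays. When each simulated array was given its own real spread instead, false calls came to 27.4%, 19.6% and 0% of calls on 12 arrays and to 13.5%, 7.06% and 2.14% on 11 arrays, so unequal arrays made the test liberal in the first and second comparisons. The number of arrays limits the precision of every value.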

Results

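Gene expression was measured in L6 dorsal root ganglia of male Fischer 344 rats on 12 one-colour arrays, 4 from each of 3 groups of rats. Young rats fed ad libitum (young_AL), old rats fed ad libitum (old_AL) and old rats under caloric restriction (old_CR) were compared to ask which inflammatory and oxidative genes differ with age in these ganglia and whether restriction offsets the difference. The group of 25 to 28 months was set against the group of 6 months with the same feeding, then old_CR against old_AL, and then old_CR against young_AL, where age and diet both differ.

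The array of old_AL 1 stood apart from the other 11. Its 75th percentile of signal was 7662, against 2634 to 3110 on the others, and 71.6% of its spots were well above background, against 78.8% to 84.1%. It held 4369 spots with uneven signal, against 1 to 215, and its median correlation with the other arrays was 0.929, against 0.971 to 0.994 on the others. Among the other 11, old_AL 4 had the lowest ratio of the 75th to the 25th percentile, 34.5 against 60.5 to 72.8, the lowest median correlation (0.971) and the lowest array weight (0.218). The planned analysis keeps all 12 arrays, and every comparison below gives its result. The typical residual spread of a gene fell from 0.357 to 0.102 on the log2 scale when this array was left out, so values on the other 11 arrays are given first, a choice made after the data were seen, with n = 3 for old_AL and n = 4 for the other groups. In simulations that gave each of the 11 arrays its own spread, false calls came to 13.5%, 7.06% and 2.14% of calls in the 3 comparisons, against the 5% aimed at. The young_AL arrays were on a slide and scan of their own, so age and slide cannot be told apart in either comparison with young rats. The old_AL arrays filled row 1 of their slide, and the old_CR and young_AL arrays filled row 2 of theirs. Row therefore cannot be told apart from diet in old rats, nor from age at ad libitum feeding.

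With age, the lists of macrophage, neutrophil and complement genes were called higher in the ganglia of ad libitum rats on the 11 arrays, and the lists of fatty acid and cholesterol synthesis genes lower, with adjusted p of 0.182 to 0.367 with an estimated correlation. Camp, an antimicrobial peptide of neutrophil granules, rose by 2.28 ± 0.20 (log2, SE, n = 3 against 4, adjusted p = 0.0034), and Ngp, another neutrophil granule protein, by 2.26 ± 0.32 (adjusted p = 0.0155). Fcna, a lectin that starts complement, rose by 2.28 ± 0.25 (adjusted p = 0.00731), and complement factor D (Cfd) by 1.995 ± 0.222 (adjusted p = 0.00768). Cfd was a member of the adipocyte list too, which camera also called higher (adjusted p = 0.00504), and the source of its rise was not tested. Gpnmb, a glycoprotein of phagocytic macrophages, rose by 1.48 ± 0.19 (adjusted p = 0.0139) and Lyve1, a hyaluronan receptor of resident macrophages and lymphatic vessels, by 1.09 ± 0.15 (adjusted p = 0.0139). The fatty acid elongase Elovl6 fell by 0.47 ± 0.05 (adjusted p = 0.0046), the stearoyl-CoA desaturase Scd by 0.44 ± 0.05 (adjusted p = 0.00768), the basement membrane collagen Col4a1 by 0.63 ± 0.08 (adjusted p = 0.0139) and the neurofilament light chain Nefl by 0.31 ± 0.04 (adjusted p = 0.0139). These 10 genes, with Acss3, a mitochondrial acyl-CoA synthetase (log2 difference −0.86 ± 0.11, adjusted p = 0.0139), passed in each of the 11 fits that left out a further array. The cholesterol carrier Stard4 did so too, at −0.38 ± 0.04 (adjusted p = 0.0046), but its second probe gave 0.09. Of 10 changes of processing, Camp passed in all and Col4a1 in 9. Fcna, Cfd, Gpnmb, Lyve1, Elovl6, Scd, Nefl, Acss3 and Stard4 passed in 8 each, and Ngp in 7 of 9. The size of some differences depended on the processing: after normexp they were 0.89 for Ngp, 1.41 for Fcna and −0.33 for Acss3, after quantile normalization −1.38 for Acss3, and with the mean of probes −0.14 for Stard4. No array value of old_AL overlapped young_AL for any of these genes on the 11 arrays, which the rule required of the genes chosen by size.

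Among the immune lists, macrophage markers had the smallest p with age on the 11 arrays. Of 25 measured members 6 rose and 19 did not pass, 21 rose when adjusted over the list alone, and the median difference was 0.82 (camera adjusted p = 3.98e-10, adjusted p = 0.28 with an estimated correlation). Besides Gpnmb and Lyve1, the scavenger receptor Cd163 rose by 1.81 ± 0.35 (adjusted p = 0.0331) and the Fc receptor Fcgr2b by 1.33 ± 0.25 (adjusted p = 0.0331), which passed in 2 and 5 of the 11 further leave-outs. Of 19 complement genes 3 rose and 16 did not pass, 10 when adjusted over the list alone. The median was 0.59 (adjusted p = 8.94e-06, adjusted p = 0.367 with an estimated correlation). The 3 were Cfd, the C1 inhibitor Serping1 (0.81 ± 0.18, adjusted p = 0.0491) and the complement brake Cd55 (0.44 ± 0.08, adjusted p = 0.0316), the last pair passing in 2 and 4 of the 11 leave-outs. Of 12 neutrophil and marrow markers 3 rose and 9 did not pass, 3 when adjusted over the list alone. The median was 1.42 (adjusted p = 0.000153, adjusted p = 0.266 with an estimated correlation). Array values of this list were 2.12 and 2.28 on old_AL 2 and 3 but 0.31 on old_AL 4, below the 0.48 of young_AL 4, and without old_AL 4 the median was 2.20. Of 17 T cell markers only Cd8a, a chain of the CD8 receptor, rose (2.21 ± 0.34, adjusted p = 0.0197), 13 when adjusted over the list alone. The median was 0.74 (adjusted p = 8.94e-06, adjusted p = 0.28 with an estimated correlation). The Cd8a call ended without young_AL 2 (adjusted p = 0.0548) and without young_AL 3 (adjusted p = 0.0611), and its difference was 0.99 after normexp. None of the 14 NK and cytotoxic cell markers passed by itself in limma, and 12 rose when adjusted over the list alone. The median was 1.31 (adjusted p = 8.94e-06, adjusted p = 0.182 with an estimated correlation). This list stood at 1.93 on old_AL 2 against 0.77 and 0.79 on old_AL 3 and 4, and without old_AL 2 its median was 0.79. Erythroid markers moved with these immune lists: 1 of 12 rose and 11 did not pass, 3 when adjusted over the list alone. The median was 0.82 (adjusted p = 0.000197, adjusted p = 0.367 with an estimated correlation), or 0.36 without old_AL 2, and the array values were 1.30, 0.41 and 0.52 on old_AL 2, 3 and 4.

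The lists of lipid synthesis, heat shock, large-diameter neuron and myelinating Schwann cell genes were called lower with age on the 11 arrays. Of 14 fatty acid synthesis genes 5 fell and 9 did not pass, and when adjusted over the list alone 9 fell and 2 rose. The median was −0.14 (adjusted p = 8.94e-06, adjusted p = 0.182 with an estimated correlation). Of 25 cholesterol synthesis genes 3 fell, among them the synthase Hmgcs1 (−0.21 ± 0.04, adjusted p = 0.0285, 6 of the 11 leave-outs), 1 rose and 21 did not pass. On all 12 arrays the difference of Hmgcs1 was positive instead. When adjusted over the list alone 12 fell and 1 rose. The median was −0.12 (adjusted p = 1.63e-09, adjusted p = 0.182 with an estimated correlation). Of 20 genes of large-diameter neurons 3 fell and 17 did not pass, 4 when adjusted over the list alone. The median was −0.08 (adjusted p = 0.00286, adjusted p = 0.28 with an estimated correlation), or −0.06 without old_AL 4 and −0.05 without young_AL 4. Those that fell were Nefl, the neurofilament heavy chain Nefh (−0.25 ± 0.05, adjusted p = 0.0388, 1 of the 11 leave-outs) and the calcium buffer Pvalb (−0.23 ± 0.04, adjusted p = 0.0331, 4 of 11). Pvalb turned on all 12 arrays, where its difference was positive. Of 15 heat shock protein genes 1 fell and 14 did not pass, 4 when adjusted over the list alone. The median was −0.10 (adjusted p = 8.04e-05, adjusted p = 0.254 with an estimated correlation). None of the 19 markers of myelinating Schwann cells, which wrap the axons, passed singly in limma, and 4 fell when adjusted over the list alone. The median was −0.17 (adjusted p = 2.3e-05, adjusted p = 0.42 with an estimated correlation).

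The question of oxidative change was addressed by 3 lists. Of 29 antioxidant defence genes only Hmox1, which breaks down heme, rose with age (0.46 ± 0.09, adjusted p = 0.0328, in 3 of the 11 leave-outs), 2 rose and 1 fell when adjusted over the list alone, and the list was not called (median 0.03, adjusted p = 0.844). None of the 9 NADPH oxidase genes, which make superoxide in phagocytes, passed singly in limma, and 3 rose when adjusted over the list alone. The median of that list was 0.45 (adjusted p = 0.00817, adjusted p = 0.367 with an estimated correlation). Its values on old_AL 2, 3 and 4 were 0.55, 0.45 and 0.23, beside 0.97, 0.96 and 0.46 for macrophage markers. These rises were not separated from each other. None of the 34 oxidative phosphorylation genes passed, whether over all genes or when adjusted over the list alone, and the list was called lower with a median of −0.03 (adjusted p = 0.0036, adjusted p = 0.558 with an estimated correlation). Quantile normalization ended this call (adjusted p = 0.0835), and the median was −0.05 without young_AL 1 and −0.02 without young_AL 2. On all 12 arrays the oxidative phosphorylation list was called in the opposite direction with a median of 0.18 (adjusted p = 0.0014, adjusted p = 0.609 with an estimated correlation), its value on old_AL 1 being 0.96.

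Camera called 23 of the 41 lists with age on the 11 arrays, 13 higher and 10 lower, and fry 16, and 0 were called with an estimated correlation. Besides those above, the lists called higher were MHC class II (adjusted p = 0.00197), cytokines (0.0036), MHC class I (0.0036), adipocyte (0.00504), B and plasma cell (0.0239) and pericyte (0.0239) genes, with adjusted p of 0.182 to 0.439 with an estimated correlation. Those called lower were potassium and calcium channel (0.0189), extracellular matrix (0.0258), pan-neuronal (0.0283) and satellite glia (0.0426) genes, with adjusted p of 0.367 to 0.558 with an estimated correlation. MHC class I lost its call without old_AL 2 (adjusted p = 0.0738) and the channels without old_AL 3 (adjusted p = 0.0577). The extracellular matrix call ended without young_AL 1, 3, 4 or old_AL 4 (adjusted p = 0.0584, 0.0633, 0.0641 and 0.405), and the pan-neuronal call without young_AL 1, 2 or old_AL 4 (adjusted p = 0.0894, 0.0602 and 0.119). The pericyte call ended without young_AL 1, old_AL 2 or old_AL 3 (adjusted p = 0.0875, 0.0835 and 0.393). The B and plasma cell call ended without young_AL 1, 4, old_AL 3, 4 or old_CR 4 (adjusted p of 0.0543 to 0.0924), and the satellite glia call without young_AL 1, 3, old_AL 2, 4 or old_CR 3 (adjusted p of 0.0543 to 0.239). Processing ended some of these calls as well. The satellite glia call ended after quantile normalization (adjusted p = 0.169), after median centring (0.07), with probes well above background on every array (0.057), with the mean of a gene's probes (0.0695) and with array weights (0.12). The extracellular matrix call ended after quantile normalization (0.4), after median centring (0.226), with the mean of probes (0.0587) and with array weights (0.539). Quantile normalization also ended the channel (0.261) and B and plasma cell calls (0.2), the latter ending with the filter on every array too (0.132). Normexp ended the MHC class I (0.0609) and pericyte calls (0.128), no filter the pericyte call (0.108) and array weights the pan-neuronal call (0.0776). The other 18 lists were not called, with adjusted p from 0.0639 for chemokines to 0.911 for cell division; these included interferon, senescence, nociceptor, nerve injury, clock, immediate early and unfolded protein genes and fibroblast, endothelial, mast cell, muscle, bone and central glia markers.

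In the planned fit of all 12 arrays, limma called 3 genes with age, of which 1 rose and 2 fell, out of 20890 tested, and 1429 had an unadjusted p under 0.05. None of the 3 had a symbol. The rise was at least 5.13-fold from a level not well above background in young_AL (adjusted p = 0.000656), and the falls were −1.61 ± 0.12 (adjusted p = 0.000816) and −1.24 ± 0.14 (adjusted p = 0.0308). Gpnmb differed by 1.68 ± 0.23 (n = 4 against 4, adjusted p = 0.0629) and Camp by 1.61 ± 0.54 (adjusted p = 0.577) there. Camera called 10 lists in that fit, 9 higher and 1 lower, with macrophage markers at an adjusted p of 9.1e-12, and 0 were called with an estimated correlation or by fry. On the 11 arrays the count was 624 of 20848, with 386 higher and 238 lower, and 78 of them changed over 2-fold. The share of calls that were higher was 61.9% on the 11 arrays, 29.2% after quantile normalization, 14.8% after median centring and 86.3% after normexp; on the 12 arrays it was 33.3%, 41.2% after quantile normalization and 60% after median centring. Leaving out young_AL 1, 2, 3 or 4 as well gave 392, 67, 79 and 307 genes. Leaving out old_AL 2, 3 or 4 gave 368, 330 and 335, and leaving out old_CR 1, 2, 3 or 4 gave 337, 307, 381 and 241. A fit of the compared groups alone called 27.

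**Figure D1:**
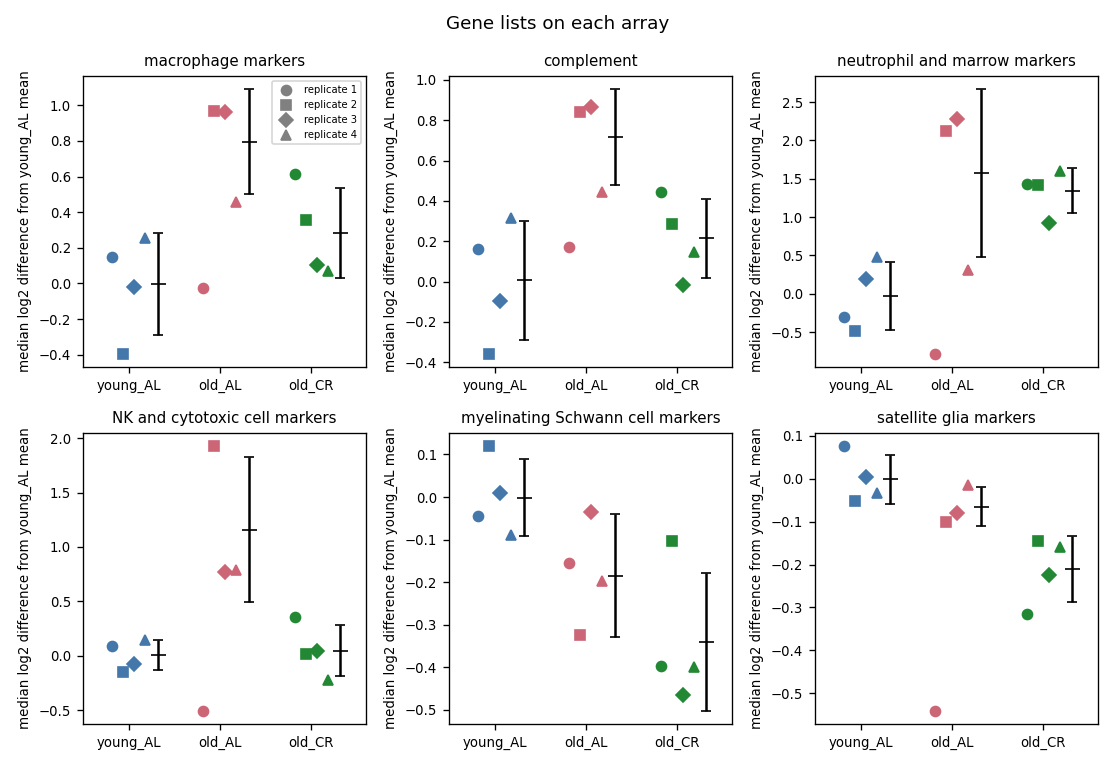
Each panel gives, for a list of genes and each of the 12 arrays, the median over its members of the log2 difference from the young_AL mean; markers tell the 4 replicates apart, and the black bar is the mean ± SD over arrays, with old_AL 1 left out. The macrophage list stood at 0.97, 0.96 and 0.46 on old_AL 2, 3 and 4 and at −0.03 on old_AL 1.

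On the 11 arrays, and not on all 12, 4 of 15 circadian clock genes differed between old_CR and old_AL. In the same fit 2 chemokine genes and 1 satellite glia marker were lower in old_CR. No label gives the hour of collection or the hours since the last meal, so neither can be told apart from an effect of restriction. Per2, a repressor of the clock, rose in old_CR against old_AL by 1.16 ± 0.09 (log2, SE, n = 4 against 3, adjusted p = 0.00864) and passed in each of the 11 fits that left out a further array, and the rise was 0.71 after normexp. The clock output factor Dbp rose by 1.13 ± 0.14 (adjusted p = 0.0315, 6 of the 11 leave-outs), its relative Tef by 0.41 ± 0.06 (adjusted p = 0.0327, 4 of 11), and the clock activator Bmal1 fell by 0.64 ± 0.10 (adjusted p = 0.0373, 3 of 11). The chemokine Cx3cl1 fell by 0.75 ± 0.09 (adjusted p = 0.0275) and the nuclear receptor Nr1h3, which senses oxysterols, by 0.48 ± 0.05 (adjusted p = 0.0255), both in 8 of the 11 leave-outs. The glutamate transporter Slc1a3 of satellite glia fell by 0.37 ± 0.05 (adjusted p = 0.032, 4 of 11). The sensory neuron transcription factor Isl1 rose by 0.31 ± 0.04 (adjusted p = 0.0317, 5 of 11).

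Of 15 clock genes 3 rose, 1 fell and 11 did not pass in old_CR against old_AL, and when adjusted over the list alone 5 rose and 3 fell. The list was not called, its median being −0.01, its mean 0.15 and its test higher (adjusted p = 0.101, and 0.0504 on all 12 arrays). Of 23 chemokines and receptors Cx3cl1 and the monocyte chemokine Ccl2 (−0.52 ± 0.09, adjusted p = 0.0444, 2 of the 11 leave-outs) fell and 21 did not pass, 2 when adjusted over the list alone. The median was −0.52 (adjusted p = 0.0428, adjusted p = 0.743 with an estimated correlation). None of the 25 macrophage markers passed in limma, over all genes or when adjusted over the list alone, and the list was called lower with a median of −0.44 (adjusted p = 0.0105, adjusted p = 0.743 with an estimated correlation). Of 19 complement genes Cd55 fell (−0.50 ± 0.08, adjusted p = 0.0373, 3 of 11) and 18 did not pass, 3 fell when adjusted over the list alone. The median was −0.48 (adjusted p = 0.0105, adjusted p = 0.743 with an estimated correlation). None of the 14 NK and cytotoxic cell markers passed singly in limma, and 10 fell when adjusted over the list alone. The median was −1.22 (adjusted p = 0.000395, adjusted p = 0.743 with an estimated correlation), and without old_AL 2, whose array value was 1.93 against 0.77 and 0.79 on old_AL 3 and 4, it was −0.51. The list of oxidative phosphorylation genes was called higher with a median of 0.04 and 0 of 34 members passing, 1 when adjusted over the list alone (adjusted p = 0.000395, adjusted p = 0.743 with an estimated correlation), and on all 12 arrays lower with a median of −0.19 (adjusted p = 0.00585, adjusted p = 0.788 with an estimated correlation). Without old_CR 3 its median on the 11 arrays was 0.02.

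The other lists called lower in old_CR against old_AL were matrix turnover (median −0.25, adjusted p = 0.0308), erythroid (−0.48, 0.0416) and pericyte (−0.24, 0.0218) genes, and those called higher were cholesterol synthesis (0.04, 0.0148), large-diameter neuron (0.07, 0.00323) and potassium and calcium channel genes (adjusted p = 0.0275). All had an adjusted p of 0.743 with an estimated correlation. The channel list had a median of 0.03 and a mean of −0.01. In all 11 of 41 lists were called by camera, 4 higher and 7 lower, 3 by fry and 0 with an estimated correlation, and the other 30 had adjusted p from 0.0771 to 0.984, among them cytokine (0.0771), neutrophil (0.676), antioxidant defence (0.676) and interferon genes (0.769). The antioxidant and interferon lists had medians of −0.01 and −0.08 and means of −0.04 and −0.11, with the test on the side of a rise. The number of called lists was 3 without old_AL 2, 5 without old_AL 3, 18 without old_AL 4 and 7 without old_CR 3. Without old_AL 2 the adjusted p was 0.134 for the macrophage, complement, chemokine, pericyte and cholesterol lists, 0.109 for matrix turnover and the channels and 0.652 for erythroid genes. Without old_AL 3 it was 0.146 for macrophage, 0.0924 for complement, 0.251 for chemokine, 0.312 for pericyte, 0.208 for matrix turnover and 0.108 for channel genes. Without old_CR 3 the macrophage, chemokine, matrix turnover and erythroid calls ended (adjusted p = 0.0553, 0.107, 0.107 and 0.107), without old_CR 4 the chemokine, channel and erythroid calls (0.0671, 0.0637 and 0.0515), and without old_CR 1 the erythroid call (0.0794). The NK, oxidative phosphorylation and large-diameter neuron lists were called in all 11 leave-outs. Medians moved to −0.26 for erythroid genes without old_AL 2 and to −0.13 for pericyte genes without old_AL 3. For cholesterol synthesis they were 0.02 without old_AL 2 or 3 and 0.06 without old_AL 4, and for the channels 0.06 without old_CR 2 and 0.02 without old_CR 3.

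Normexp ended the macrophage (adjusted p = 0.0656), complement (0.0807), chemokine (0.0807), matrix turnover (0.131), erythroid (0.0656) and pericyte calls (0.115) in old_CR against old_AL. Without a filter on dim probes the chemokine (0.112), matrix turnover (0.0982), erythroid (0.0904) and pericyte calls (0.0632) ended, with probes well above background on every array the matrix turnover call (0.0736), and with array weights the erythroid call (0.102). Quantile normalization ended the cholesterol synthesis (0.45) and channel calls (0.328).

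Single genes from other lists changed as well in old_CR against old_AL. The matrix protein Postn fell by 1.44 ± 0.27 (adjusted p = 0.0447, 0 of the 11 leave-outs), the cyclin-dependent kinase inhibitor Cdkn1a by 0.35 ± 0.07 (adjusted p = 0.0477, 1 of 11), the prostaglandin receptor Ptger4 by 0.46 ± 0.07 (adjusted p = 0.0321, 5 of 11) and the lipase inhibitor Angptl4 by 0.49 ± 0.08 (adjusted p = 0.0418, 2 of 11). The water channel gene Aqp4 rose by 1.003 ± 0.160 (adjusted p = 0.0373, 2 of 11) at its brightest probe, its second probe gave −0.28 and the mean of probes 0.36. After quantile normalization Ptger4 differed by −0.07. The sensory neuron factor Pou4f2 rose by 0.26 ± 0.05 (adjusted p = 0.0447, 2 of 11).

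In the planned fit of all 12 arrays limma called 0 of 20890 genes in old_CR against old_AL. The smallest adjusted p was 0.109, and 1291 genes had an unadjusted p under 0.05, 305 higher and 986 lower. Per2 differed there by 1.48 ± 0.26 (n = 4 against 4, adjusted p = 0.479) and Dbp by 1.03 ± 0.16 (adjusted p = 0.282). Camera called 9 lists lower and 0 higher in that fit, among them complement, macrophage and NK genes (adjusted p = 0.00185 each), and 0 were called with an estimated correlation or by fry. On the 11 arrays 222 of 20848 genes were called, 54 higher and 168 lower. The share that was higher was 24.3%, against 56.4% after quantile normalization, 84.7% after median centring and 10.6% after normexp. Leaving out a further array, the count was 123, 15, 7 and 79 without young_AL 1, 2, 3 and 4. It was 931, 218 and 2 without old_AL 2, 3 and 4, and 21, 40, 15 and 1 without old_CR 1, 2, 3 and 4. A limma fit of old_CR and the 3 old_AL arrays alone called 0 genes, with 4668 at an unadjusted p under 0.05.

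**Figure D2:**
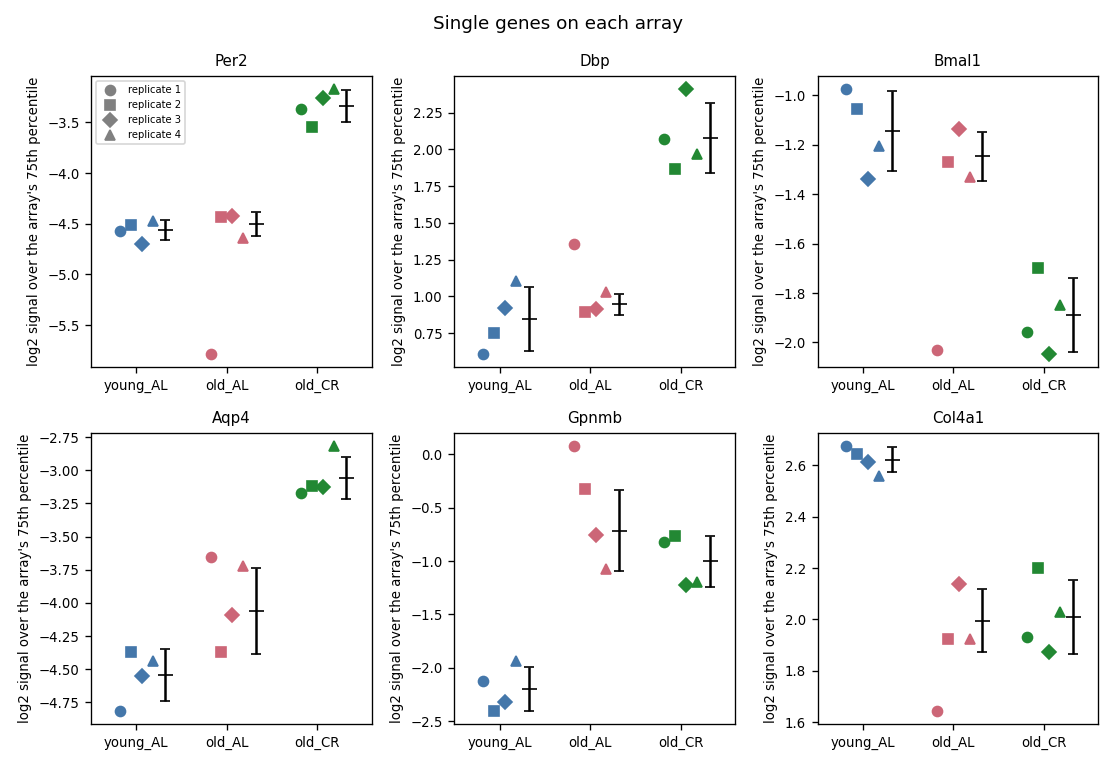
Each panel gives the log2 signal of a gene over the array's 75th percentile on the 12 arrays, with markers for the 4 replicates of a group and a black bar for the mean ± SD, old_AL 1 left out. Per2 and Dbp lay higher and Bmal1 lower on every old_CR array than on old_AL 2, 3 and 4, and Gpnmb higher on those arrays than on every young_AL array.

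Of the genes called with age on the 11 arrays, 99 were also called in old_CR against old_AL in the opposite direction and 0 in the same direction. They comprised 79 genes higher with age and lower under restriction and 20 of the reverse kind, where lists called independently would share 3.11 and 0.616. Among the first kind were Cd55, Postn, Nr1h3, the integrin chain Itga5 (0.98 ± 0.15 with age, −0.84 ± 0.15 with restriction, the latter in 2 of 11 leave-outs) and the ubiquitin ligase Fbxo32 (0.40 ± 0.06 and −0.43 ± 0.06, 4 of 11), and among the second Isl1, Pou4f2 and the malic enzyme Me1 (−0.21 ± 0.04 and 0.21 ± 0.04, 2 of 11). With restriction, quantile normalization gave −0.31 for Itga5 and −0.04 for Fbxo32, and on all 12 arrays the difference of Me1 was negative instead. The second probe of Me1 gave −0.23 with age and 0.08 with restriction on the 11 arrays, and −0.15 in old_CR against young_AL. Both comparisons hold the old_AL arrays. These alone lie in row 1 of a slide, so a difference by row would also look like a change back. In 100 simulations of unchanged groups the mean overlap was 0.02 genes, and the correlation of the differences across genes, which are not independent replicates, was −0.569 against −0.684 in the data. With no gene changed few can pass in either comparison, so that low overlap does not test what the shared old_AL arrays add. The covariance was −0.0330 in the simulations and −0.0763 in the data, a difference of −0.0433. The simulations gave every array the same spread. In the data the array weights were 0.614, 2.06 and 0.218 on old_AL 2, 3 and 4, against 0.779 to 2.43 on the others. A lower weight stands for a noisier array. Noise of the shared old_AL arrays enters both comparisons, so the gaps in correlation and covariance cannot be read as a change back. When 2 old_AL arrays picked 200 age genes and the remaining one was set against old_CR, 72.5% of those genes moved back (range 68.5% to 75.5% over 3 splits). No such share was computed for genes not picked. The median difference of all genes on the 11 arrays was 0.035 with age and −0.056 with restriction, so the share cannot be read as a reversal of single genes. In the planned fit of 12 arrays 0 genes were called in both comparisons by limma, from 3 and 0 calls, with 1429 and 1291 at an unadjusted p under 0.05, and the share that moved back was 47% (range 40.5% to 71.5% over 6 splits). Leaving out young_AL 1, 2, 3 or 4 from the 11 arrays gave 56, 2, 3 and 31 such genes, leaving out old_AL 2, 3 or 4 gave 190, 122 and 1, and leaving out old_CR 1, 2, 3 or 4 gave 14, 16, 3 and 0.

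Old restricted ganglia also differed from young ones, with age and slide not separable. Of the genes that follow, Dbp, Bmal1 and Slc1a3 differed by 0.10, −0.10 and −0.04 at their brightest probes in old_AL against young_AL on the 11 arrays. Camp, Col4a1, Elovl6 and Ednrb had passed in that comparison too. Camp rose in old_CR against young_AL on the 11 arrays by 1.69 ± 0.19 (log2, SE, n = 4 against 4, adjusted p = 0.00657). Per2 rose by 1.23 ± 0.09 (adjusted p = 0.00135), Dbp by 1.23 ± 0.13 (adjusted p = 0.00606) and Tef by 0.47 ± 0.06 (adjusted p = 0.0101), and Bmal1 fell by 0.75 ± 0.10 (adjusted p = 0.012). Carbonic anhydrase 4 (Car4) fell by 1.99 ± 0.26 (adjusted p = 0.012), Col4a1 by 0.61 ± 0.08 (adjusted p = 0.0107) and Slc1a3 by 0.40 ± 0.05 (adjusted p = 0.0101). The endothelin receptor Ednrb fell by 0.41 ± 0.05 (adjusted p = 0.0128) and Elovl6 by 0.35 ± 0.04 (adjusted p = 0.0102). These genes passed in each of the 11 leave-outs. Aqp4 did so too, with a rise of 1.49 ± 0.15 at its brightest probe (adjusted p = 0.00531) and 0.03 at its second, or 0.76 with the mean of probes. After normexp Car4 differed by −0.59. Adipoq, the fat cell hormone adiponectin, rose at least 7.37-fold (adjusted p = 0.0265, 3 of the 11 leave-outs) and the clock gene Ciart at least 4.04-fold (adjusted p = 0.0269, 5 of 11), from levels not well above background in young_AL. These bounds hold for the scaling to the 75th percentile, and after normexp the log2 differences were 0.91 for Adipoq and 0.45 for Ciart, below them.

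The clock list was called higher in old_CR against young_AL, with 5 of 15 genes that rose, 1 that fell and 9 that did not pass, and 6 and 3 when adjusted over the list alone (median 0.14, adjusted p = 0.000772, adjusted p = 0.113 with an estimated correlation). Of 25 macrophage markers 4 rose and 21 did not pass, 6 when adjusted over the list alone. The median was 0.27 (adjusted p = 2.32e-06, adjusted p = 0.434 with an estimated correlation), or 0.17 without old_CR 1 and 0.14 without young_AL 2. The risen markers included Gpnmb (1.19 ± 0.18, adjusted p = 0.0166, 9 of the 11 leave-outs), Lyve1 (0.82 ± 0.13, adjusted p = 0.0213, 5 of 11) and Fcgr2b (1.32 ± 0.23, adjusted p = 0.0265, 5 of 11), whose second probe gave 0.16 and the mean of probes 0.74. Of 12 neutrophil and marrow markers Camp rose and 11 did not pass, 5 when adjusted over the list alone. The median was 1.33 (adjusted p = 3.01e-05, adjusted p = 0.246 with an estimated correlation), beside 0.31 for erythroid markers, which were not called (adjusted p = 0.102). Of 17 satellite glia markers 6 fell and 11 did not pass, 8 when adjusted over the list alone, among them Slc1a3, Ednrb and the lipid carrier Fabp7 (−0.61 ± 0.11, adjusted p = 0.0282, 4 of 11). The median was −0.16 (adjusted p = 6.77e-05, adjusted p = 0.136 with an estimated correlation). Of 19 markers of myelinating Schwann cells Ugt8 and Fa2h, which make myelin lipids, fell (−0.73 ± 0.14 and −0.52 ± 0.10, adjusted p = 0.0308 and 0.0358, each in 4 of 11) and 17 did not pass, 13 when adjusted over the list alone. The median was −0.35 (adjusted p = 9.15e-07, adjusted p = 0.434 with an estimated correlation). Of 18 extracellular matrix genes 4 fell and 14 did not pass, 8 when adjusted over the list alone, among them Col4a1 and Col1a1 (−0.92 ± 0.15, adjusted p = 0.021, 6 of 11). The median was −0.20 (adjusted p = 3.01e-05, adjusted p = 0.434 with an estimated correlation), or −0.13 without old_CR 3. Of 13 adipocyte markers 3 rose and 10 did not pass, and 5 rose and 1 fell when adjusted over the list alone (median 0.20, adjusted p = 0.000136, adjusted p = 0.113 with an estimated correlation). The median of this list was 0.13 without old_CR 3 and 0.09 without young_AL 1.

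The lists of fatty acid and cholesterol synthesis genes were also called lower in old_CR against young_AL. Of 14 fatty acid synthesis genes 4 fell, among them Elovl6 and the desaturase Fads2 (−0.33 ± 0.05, adjusted p = 0.0191, 6 of 11), and 10 did not pass, 4 when adjusted over the list alone. The median was −0.08 (adjusted p = 0.000655, adjusted p = 0.246 with an estimated correlation). Of 25 cholesterol synthesis genes 2 fell, 1 rose and 22 did not pass, 11 and 1 when adjusted over the list alone. The median was −0.12 (adjusted p = 3.01e-05, adjusted p = 0.359 with an estimated correlation). The T cell (adjusted p = 6.77e-05), complement (0.0274) and glucocorticoid and fasting response (0.0419) lists were called higher and the heat shock (0.00361) and immediate early (0.00321) lists lower, with adjusted p of 0.434 to 0.794 with an estimated correlation. The complement call ended without young_AL 2 or 3 or old_CR 1 or 2 (adjusted p = 0.335, 0.0597, 0.138 and 0.0938), and the fasting list kept its call in 4 of the 11 leave-outs, with adjusted p of 0.0542 to 0.115 in the other 7. It also ended with probes well above background on every array (0.0516) and with the compared groups alone (0.0556). In all camera called 14 of 41 lists, 7 higher and 7 lower, fry 9, and 0 with an estimated correlation, and the other 27 had adjusted p from 0.0517 to 0.994, among them NK markers (0.664).

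In the planned fit of all 12 arrays limma called 3 genes in old_CR against young_AL, and 581 had an unadjusted p under 0.05. They were Aqp4 (1.49 ± 0.17, adjusted p = 0.0266), a gene without a symbol that was at least 4.34-fold higher (adjusted p = 0.00152) and another without a symbol that fell (−1.31 ± 0.12, adjusted p = 0.00623). Both unnamed genes were among those called with age. The second probe of Aqp4 gave 0.03. Its call on the 12 arrays ended after quantile normalization (adjusted p = 0.188), median centring (0.212) and normexp (0.0501) and with the mean of probes (0.331). It ended without young_AL 1, 2, 3 or 4 (0.132, 0.0885, 0.165 and 0.0689), without old_AL 3 (0.0677) and without old_CR 1, 2, 3 or 4 (0.119, 0.121, 0.136 and 0.112). Camera called 17 lists there, 10 higher and 7 lower; with an estimated correlation the satellite glia list alone was called (adjusted p = 0.0165), and fry called 0. On the 11 arrays 484 of 20848 genes were called, 157 higher and 327 lower. Leaving out a further array gave 144, 144, 40 and 414 without young_AL 1, 2, 3 and 4, then 603, 375 and 875 without old_AL 2, 3 and 4, and 96, 254, 186 and 84 without old_CR 1, 2, 3 and 4. The share of calls that were higher was 32.4%, against 32.3% after quantile normalization and 29.1% after median centring on the 11 arrays, and on the 12 arrays it was 66.7%, against 50% after either.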

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

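The results on 11 arrays and the tests of the patterns of old_AL 1, of NK genes and of clock genes were chosen after the values were seen, whereas the counts of other splits of the samples were planned. A sample is listed here when its gap to the nearest of the 4 arrays of its group, as a share of the group's range, passed Dixon's 95% limit for 4 samples, which chance passes in about 1 of 20 groups. This held for 9 of 24 array measures, 19 of 123 list values and 14 of 165 gene values, and old_AL 1 was the far array in 6, 15 and 2 of them. For genes named only on the 11 arrays the old_AL group was not tested, so old_AL 1 could not be listed for those genes.

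Within old_AL, the array of old_AL 1 stood highest in the 75th percentile of signal (0.977), the 99th percentile (0.984), uneven spots (0.954), outlier spots (0.921), bright corner controls (0.949) and an E1A spike-in control (0.986). It was the highest of its group for antioxidant defence (0.908), oxidative phosphorylation (0.941), fatty acid synthesis (0.927), heat shock (0.877), unfolded protein (0.946), nociceptor (0.893) and pan-neuronal genes (0.917). It was the lowest for cytokines (0.923), interferon-stimulated genes (0.857), clock genes (0.891), cell division (0.859), nerve injury (0.859), satellite glia (0.838), mast cells (0.968), adipocytes (0.970) and Per2 (0.843), and the highest for Bdnf (0.904).

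Young_AL 4 had the most uneven spots (0.976) and outlier spots (0.932) and the lowest median correlation with the other arrays (0.972) of its group, at 215, 707 and 0.985. Among lists, young_AL 1 was far above its group for nerve injury genes (0.927), old_CR 2 below it for potassium and calcium channels (0.892) and above it for bone and cartilage markers (0.914), and old_CR 3 below it for extracellular matrix genes (0.879). Among genes of old_CR, Reg3a (0.890) and Reg3b (0.865) were high on old_CR 3, Hmox1 (0.838) on old_CR 2 and Aqp4 (0.859) on old_CR 4, and Scrg1 was low on old_CR 4 (0.932). In old_AL, Cd55 was low on old_AL 3 (0.834) and Wee1 on old_AL 4 (0.965). In young_AL, Nefl (0.879) and Lima1 (0.875) were low on young_AL 3, Nefh (0.868) and Adipoq (0.867) on young_AL 4 and Me1 on young_AL 1 (0.853).

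The array of old_AL 1 differed from the other 11 in signal and in many lists. A difference in the RNA of this animal alone was argued against by the bright corner controls, which carry no rat sequence and read 555780 there against at most 63104 elsewhere. A fault of the array or its hybridisation remained open, since 4369 of its spots were uneven against at most 215 on the others. A fault does not exclude a difference in the RNA as well, and the data hold no repeat of this sample.

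NK and cytotoxic cell genes stood higher on old_AL 2 than on the higher of old_AL 3 and 4 by 1.14. For carried-over blood of usual make-up the lists pointed both ways. Against the higher of those arrays the B and plasma cell list differed by −0.489 and the neutrophil list by −0.159, but the erythroid list by 0.786. The test therefore does not decide on blood. A shift of dim signals across the array was argued against by the T cell, B cell, macrophage and mast cell lists, whose largest gap was 0.0198. An expansion of granular lymphocytes in this rat remained open as a hypothesis, found and tested on the same data, and the erythroid list was higher there too, by 0.786.

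Per2 and Dbp were higher and Bmal1 lower in old_CR than in old_AL under 4 scalings on 12 and on 11 arrays. Scaling between arrays was argued against by the smallest rise of Per2, 0.71, with Dbp at 0.94 to 1.22 and Bmal1 at −0.64 to −0.41. The hour of collection and the hours since the last meal cannot be told apart from an effect of restriction on the clock, of which 4 list members passed on the 11 arrays, because no label gives either hour and old_CR was fed on 3 days a week.

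Other splits of the samples into groups of the same sizes were counted, 35 for each comparison, with the real split included. On the 11 arrays no other split reached the real gene counts. For age 1 of 35 splits gave as many (624, highest other 64). For old_CR against old_AL it was 1 of 35 (222, highest other 2), and for old_CR against young_AL 1 of 35 (484, highest other 1). A share of 1 of 35 is the smallest that these splits can give. The 11 arrays were also chosen after the values were seen, so chance is argued against and not excluded. On the 11 arrays the 99 genes that changed back were reached by 1 of 100 regroupings (highest other 1). Regrouping breaks up the real groups, so few genes pass in either comparison and a low overlap was all but fixed. The count does not separate a change back from what the shared old_AL arrays add. Chance cannot be excluded there for the number of called lists, reached by 5 of 35 splits for age (23, highest other 24), 17 of 35 for old_CR against old_AL (11, highest other 27) and 15 of 35 for old_CR against young_AL (14, highest other 20).

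On all 12 arrays 1 of 35 splits reached the 3 genes of old_CR against young_AL (highest other 0), again the smallest share possible. Chance cannot be excluded for the 3 genes of age, which 2 of 35 splits reached (highest other 4). Limma's counts of 0 in old_CR against old_AL (1291 genes at an unadjusted p under 0.05) and of genes changed back are reached by any split, so the 35 of 35 splits and 100 of 100 regroupings (highest other 0 in both) say nothing about chance. For the lists 17 of 35 splits reached the 10 of age (highest other 21), 13 of 35 the 9 of old_CR against old_AL (highest other 18) and 14 of 35 the 17 of old_CR against young_AL (highest other 23), so chance cannot be excluded for them either.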

How the results depend on the processing

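The fits on 11 arrays, with array weights, without old_AL 1, 4 and young_AL 4 and without old_AL 1 and 2 were chosen after the values were seen. Values below are in the order age, old_CR against old_AL and old_CR against young_AL unless named, and for changed results the cause was not tested unless given.

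On the 12 arrays 376 of 474 values of genes under alternatives kept their direction and side of the threshold, 14 fell short of it, 84 newly passed it and 0 turned. Of 3321 values of lists 2824 kept both, 170 fell short, 135 newly passed, 17 turned and 175 turned without passing in either fit. The numbers on the 11 arrays were 1329, 702, 0 and 7 of 2038 for genes and 2625, 181, 119, 4 and 146 of 3075 for lists. Of 89 calls of named genes on the 11 arrays, counted per gene and comparison, 79 were kept after quantile normalization, 87 after median centring and 84 after normexp. Without a filter 67 were kept, with array weights 88, with the mean of probes 81 and with the compared groups alone 31. On all 12 arrays 1 was kept, 6 turned and 82 did not pass. Signal over background set which genes were tested.

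On the 12 arrays genes called with age and in old_CR against young_AL numbered 17 and 2 after quantile normalization, 5 and 1 after median centring and 0 and 0 after normexp with limma (1362 and 392 at an unadjusted p under 0.05). Without a filter they were 76 with age and 5 in old_CR against old_AL, 3 changed back, the share that moved back was 80.5% and 2 lists were called in old_CR against old_AL. With probes well above background on every array 6 genes were called with age, and with the compared groups alone 1 with age and 855 in old_CR against young_AL. Array weights gave 1558, 1977 and 2088 genes, 629 changed back and 22 and 20 lists. With an estimated correlation 0, 0 and 1 lists were called, and with fry 0, 0 and 0. Without old_AL 1, 4 and young_AL 4 there were 257, 6 and 728 genes, 2 changed back and 23 and 19 lists. Without old_AL 1 and 2 there were 368, 931 and 603, 190 changed back and 20 and 3 lists.

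On the 11 arrays quantile normalization gave 1119 and 505 genes for the first comparisons, 237 changed back and a share of 64.5%. Median centring gave 2427 and 1464, 719 changed back, a share of 66.5% and 19 lists in old_CR against old_AL, and normexp gave 3797 and 4693, 2574 changed back, 93% and 5 lists there. Without a filter 123 genes were called in old_CR against old_AL and 211 in old_CR against young_AL, with a share of 83.5%, and with the filter on every array 343 in old_CR against old_AL and 76.5%. The compared groups alone gave 27, 0 and 855 genes and 0 changed back, with 3671, 4668 and 4737 at an unadjusted p under 0.05 in limma. Array weights gave 1554, 2302 and 1914, 660 changed back and 17 lists in old_CR against old_AL, and an intensity trend 1080, 856 and 748 and 329 changed back. With an estimated correlation 0, 0 and 0 lists were called, and with fry 3 in old_CR against old_AL and 9 in old_CR against young_AL. With 100 genes picked the share was 77%. All 12 arrays gave 3, 0 and 3 genes, 0 changed back, 47% and 10 lists with age.

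Leaving out 1 array, the 12 arrays gave 2 to 624, 0 to 222 and 1 to 484 genes, 0 to 99 changed back, a share of 40% to 72.5% that moved back and 6 to 23, 1 to 13 and 13 to 20 lists. The 11 arrays gave 67 to 392, 1 to 931 and 40 to 875 genes, 0 to 190 changed back, a share of 69.5% to 76.5% and 20 to 24, 3 to 18 and 12 to 18 lists. The share was not computed with 2 old_AL arrays left.

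Some results turned. On the 12 arrays oxidative phosphorylation turned with age after quantile normalization (adjusted p = 0.689), with array weights (0.00224), without old_AL 1, 4 and young_AL 4 (0.00505) and without old_AL 1 and 2 (0.0129), and in old_CR against old_AL in the same fits (0.273, 0.000598, 0.000118 and 0.00472). Without old_AL 1, 4 and young_AL 4 the fatty acid (0.0483), cell division (0.0176) and neutrophil lists (0.00751) turned in old_CR against old_AL, and without old_AL 1 and 2 the pan-neuronal list with age (0.0223). Leaving out 1 array, adjusted p spanned 5.46e-05 to 0.00602 and 0.0283 to 0.981 for oxidative phosphorylation and pan-neuronal genes with age. It spanned 0.000275 to 0.00865 for oxidative phosphorylation in old_CR against old_AL and 1.16e-05 to 0.223 and 0.00119 to 0.827 for interferon and nerve injury genes in old_CR against young_AL, the last being 0.0171 to 0.907 on the 11 arrays. Sox2 turned with the mean of its probes (0.17). Against the 11 arrays, the 12 turned Trpa1 (−0.12), Hmgcs1 (0.054) and Pvalb (0.11) with age, Me1 (−0.24), Sox18 (0.43) and Lima1 (0.25) in old_CR against old_AL, and oxidative phosphorylation (0.0014 and 0.00585) and pan-neuronal genes (0.785).

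The replicate numbers of the source names are shared between groups and equal the slide column of each array, so a replicate block is also a block by column. No strong pairing was seen: 0 of 12 pairs had a correlation of deviations over 0.1 (range −0.065 to 0.084). The own number correlated best in 4 of 12 pairs. Between old_AL and old_CR, which share a slide, the correlations were 0.084, 0.082, 0.037 and 0.059 for replicates 1 to 4. There the own number was best for replicates 1, 2 and 4. The numbers in the titles were not tested. With a replicate block the 12 arrays gave 2, 0 and 2 genes and the 11 arrays 20, 1 and 21, with 1 changed back. The block kept 6 of the 89 calls of named genes and ended the call of Aqp4 on the 12 arrays in limma (adjusted p = 0.266). It ended the calls of pan-neuronal (adjusted p = 0.0531) and satellite glia genes (0.101) with age and of erythroid genes in old_CR against old_AL (0.0568). A slide block was not run, since young_AL has a slide of its own and the diet comparison lies within a slide, where row goes with diet.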

Other observations

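The genes in this part were read on the 11 arrays, a set of arrays chosen after the values were seen. Further genes changed with age in old_AL against young_AL. Reg3a, a secreted lectin, rose by 2.62 ± 0.37 (log2, SE, n = 3 against 4, adjusted p = 0.0154, 10 of the 11 leave-outs, 0.0512 without young_AL 2) and Reg3b, its relative, by 2.15 ± 0.41 (adjusted p = 0.0331, 3 of 11). The clock repressor Bhlhe40 rose by 0.42 ± 0.06 (adjusted p = 0.0174, 9 of 11), the irritant channel Trpa1 by 0.43 ± 0.09 (adjusted p = 0.0463, 0 of 11) and Postn by 1.57 ± 0.27 (adjusted p = 0.0264, 10 of 11, 0.0544 without old_AL 2). The neurokinin receptor Tacr3 fell by 0.98 ± 0.19 (adjusted p = 0.0328, 5 of 11), the serotonin receptor Htr1b by 0.75 ± 0.15 (adjusted p = 0.0398, 2 of 11) and Mrgprd, a receptor of nonpeptidergic nociceptors, by 0.42 ± 0.09 (adjusted p = 0.0481, 1 of 11). After normexp the differences were −0.06 for Tacr3, −0.20 for Htr1b and −0.24 for Mrgprd, and after quantile normalization −1.38 for Htr1b, −0.66 for Mrgprd and 0.25 for Bhlhe40.

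In old_CR the growth factor Bdnf fell against old_AL by 0.65 ± 0.09 (adjusted p = 0.0317) and against young_AL by 0.60 ± 0.09 (adjusted p = 0.0151), and the cell cycle kinase Wee1, a clock target, rose by 0.45 ± 0.06 (adjusted p = 0.0317) and 0.54 ± 0.06 (adjusted p = 0.00533). The calls of Bdnf and Wee1 were not followed through the leave-outs of the 11 arrays, so how stable they are is not known. Against young_AL the matrix protein Tnc fell by 0.95 ± 0.17 (adjusted p = 0.0265, 5 of the 11 leave-outs), the chaperone Hsph1 by 0.38 ± 0.07 (adjusted p = 0.0347, 3 of 11), and the fasting-induced factor Klf15 rose by 0.69 ± 0.15 (adjusted p = 0.047, 3 of 11).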
